A study of Mus musculus with 29 samples.

How the data were processed

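Bulk RNA sequencing measured gene expression in microglia that had been sorted from the brains of male C57BL/6J mice, 1 library per sample and 29 libraries in 6 groups. Per the labels, perfused brains without olfactory bulbs were dissociated mechanically on ice, myelin was removed on a Percoll gradient, and live cells with high CD11b, intermediate CD45 and no Ly6C on their surface were sorted on one of 2 instruments, a MoFlo Astrios or a MoFlo XDP. Ly6C marks inflammatory monocytes, so the gate leaves most of them out. RNA was isolated with a micro-scale column kit, libraries were made with a low-input kit that starts from polyadenylated RNA, and sequencing was done on a NovaSeq6000 instrument, per the labels.

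The deposited count table holds whole-number read counts per gene that the authors did not normalize. FastQC 0.11.9, cutadapt 2.10, TopHat, SAMtools 1.10, Picard 2.13.2 and HTSeq 0.11.0 are named in the submitters' processing notes, with the mouse build GRCm39. The notes give these names without role or order, and the version of TopHat, the gene annotation release and the strand setting of the counting are not given in the sources used here. Without a stated strand setting, reads of a gene and of an overlapping antisense gene cannot be told apart, and near-identical gene copies such as the alpha globins, the beta globins and the classical MHC class I genes H2-K1 and H2-D1 can share reads, so values of such genes are uncertain. The deposited sample table gives an RNA quality number, a score of RNA integrity on which higher is better, and the RNA concentration and sorting day of each library, as the authors recorded them. The reference genome at hand was of another build than the counts, so no coordinates were taken from it, and genes are identified by the symbol, Ensembl identifier and chromosome that the count table gives.

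The table lists 36982 genes, of which 4744 had no count in any library and 1323 had no Ensembl identifier; the latter held 1.29% of all counts and were kept under their symbols. Total counts per library lay between 5670450 and 12671476, with a median of 7597841. At this depth a gene with 0 counts in all libraries of a group is below 0.0756 CPM (counts scaled to library size) in PP, 0.0713 in PBP, 0.101 in PL, 0.0972 in PBL, 0.07 in LL and 0.0775 in LBL, the level of 3 counts over the group; these limits cover counting error only. A fold against such a group is given as a bound, computed at that level. Every pair of libraries of one group was compared for duplication over genes with at least 20 counts in the pair: the 56 pairs had a chi-square per degree of freedom between 5.47 and 32.45, so no pair agreed within sampling noise and each library was counted as 1 replicate.

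Genes were tested with edgeR 4.0.16 in R 4.3.3: genes with low counts were removed with filterByExpr at its defaults, which left 16632 genes, libraries were scaled by TMM, and a quasi-likelihood model with robust dispersion was fitted to all 29 libraries with 1 coefficient per group, leaving 23 residual degrees of freedom. The common biological coefficient of variation was 0.26. Log2 fold changes are given with their standard errors (SE), p-values are two-sided and were adjusted by the Benjamini-Hochberg procedure over the genes of a comparison, and genes with an adjusted p under 0.05 were called. Sorter and sorting day were not in this model, because they nearly coincide with the groups. CPM values use TMM-scaled library sizes and are given as mean ± SD over the libraries of a group. The labels do not say more about the animals than 1 sample each, so p-values measure the spread between these samples.

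Gene lists were tested with camera from limma 3.58.1 at its preset correlation of 0.01 between genes and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison. The lists were inflammatory cytokines and chemokines, interferon-stimulated genes, NF-kB targets and negative feedback regulators, TLR4 signalling components, homeostatic microglia genes, disease-associated and primed microglia genes, MHC class I and class II antigen presentation, complement and Fc receptors, cell cycle, glycolysis and HIF1A targets, nuclear-encoded oxidative phosphorylation, cholesterol synthesis and SREBP2 targets, immediate early and heat shock genes, and markers of monocytes, border-associated macrophages, neutrophils, lymphocytes, astrocytes, oligodendrocytes, neurons, endothelial cells and pericytes, and red blood cells. For each, members called higher or lower were counted with adjustment over all genes and over the list alone. For the cell type lists and the immediate early list, the mean log2 CPM (prior count 2) of the members was taken per library. Groups were compared by an exact two-sided permutation test, unadjusted unless stated. Lists of LPS-responsive genes (adjusted p under 0.05 and a log2 fold change of at least 1 in size) were taken from the mice with or without depletion and tested in the other mice, so that no library both defined a list and was tested on it, and their p-values were adjusted over the 4 tests.

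Named genes followed a rule: in each comparison, the 8 largest rises and the 8 largest falls among called genes with a mean of at least 5 CPM and no overlap between the groups' libraries (no such condition for interactions), without predicted gene models; up to 4 members of each list, namely the 3 with the smallest adjusted p and the one that moved most against the rest; and a fixed panel of inflammatory and microglial genes. Il10, which belonged to the panel, did not pass the filter on low counts and was not tested. A few genes that the rule names are not reported. The groups, lists, naming rule, tests and most alternatives were chosen before the data were examined.

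The alternatives were DESeq2's size factors (RLE), no filter on low counts, the replicate number as a block, the sorter as a covariate, a fit on only the groups compared, limma voom with quality weights, DESeq2 1.42.0 with its Wald test, and leaving out each library in turn. Sorting day, RNA quality number and the neuron list score as covariates, fits within 1 sorting day or 1 sorter, and a few variants of the list tests were added after seeing the data. For each comparison, 50 of the possible splits of its libraries into groups of the same sizes were fitted and their calls counted. Counts were simulated from the real means and depths of the tested genes, with 200 genes changed by known folds. These 200 genes all lay above a minimum mean count, so changes in genes near the floor were not covered. The gene test was run on the simulated counts. In the simulation of PBP against PP (16225 genes in the fit) it called 26.9% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 97% of those changed 4-fold; in that of the interaction of earlier LPS with depletion (16181 genes) the shares were 8.96%, 58.2% and 90.9%. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 prepared the tables, and matplotlib 3.10.9 drew the figures.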

Results

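Microglia were profiled from male mice that received 2 intraperitoneal injections 5 weeks apart, the first at 10 weeks of age. Each injection was either saline (P) or 1 mg/kg lipopolysaccharide (L, LPS), the bacterial cell wall component sensed by Toll-like receptor 4. From 1 week after the first injection, some mice were given BLZ945 (B) by mouth for 5 days at 169 mg/kg per day and the others vehicle. BLZ945 blocks CSF1R, the receptor on which microglial survival depends, so that these mice lost microglia and were repopulated by new ones before the second injection. Brains were taken 3 h after the second injection, at 15 weeks. The groups, named by first injection, depletion and second injection, were PP (n = 5), PBP (n = 5), PL (n = 4), PBL (n = 5), LL (n = 5) and LBL (n = 5), 29 libraries in total. The series asks whether microglia that grew back after depletion still carry a memory of the earlier LPS.

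Total counts per library were 7397399 to 8606743 in PP, 5745164 to 11198323 in PBP, 5806269 to 9056425 in PL, 5670450 to 7287523 in PBL, 6404550 to 12671476 in LL and 6111284 to 9612363 in LBL. The first principal component held 40.1% of the variance and ran from the PP libraries (-98.8 to -61.4) to the PBL libraries (60.8 to 92.5), and the second held 11.5%, with PL at 46.6 to 74.5. PBP replicate 5 lay at -1.8 on the first component, away from the other PBP libraries (-86.4 to -64.7). The mean RNA quality number was 8.86 ± 0.182 (SD) in PP, 8.6 ± 0.678 in PBP, 8.225 ± 1.187 in PL, 7.64 ± 0.207 in PBL, 8.24 ± 0.422 in LL and 8.36 ± 0.541 in LBL.

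Sorting day and sorter nearly coincided with the groups. PP (5 libraries) and 2 of PL were sorted on day 5 and the other 2 of PL on day 4 with 4 of PBP, all on the Astrios, whereas PBL (5) and PBP replicate 5 were sorted on day 3, and LL and LBL on days 1 and 2, on the XDP. The neuron marker score, a mean log2 CPM, was 1.19 ± 0.63 in PP (SD), 2 ± 1.23 in PBP, 1.85 ± 0.42 in PL, 4 ± 0.32 in PBL, 3.31 ± 0.65 in LL and 3.88 ± 0.54 in LBL, higher in the groups sorted on the XDP. PBP replicate 5 had a neuron score of 4.02, against 0.99 to 2.3 in the other PBP libraries.

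**Figure D1:**
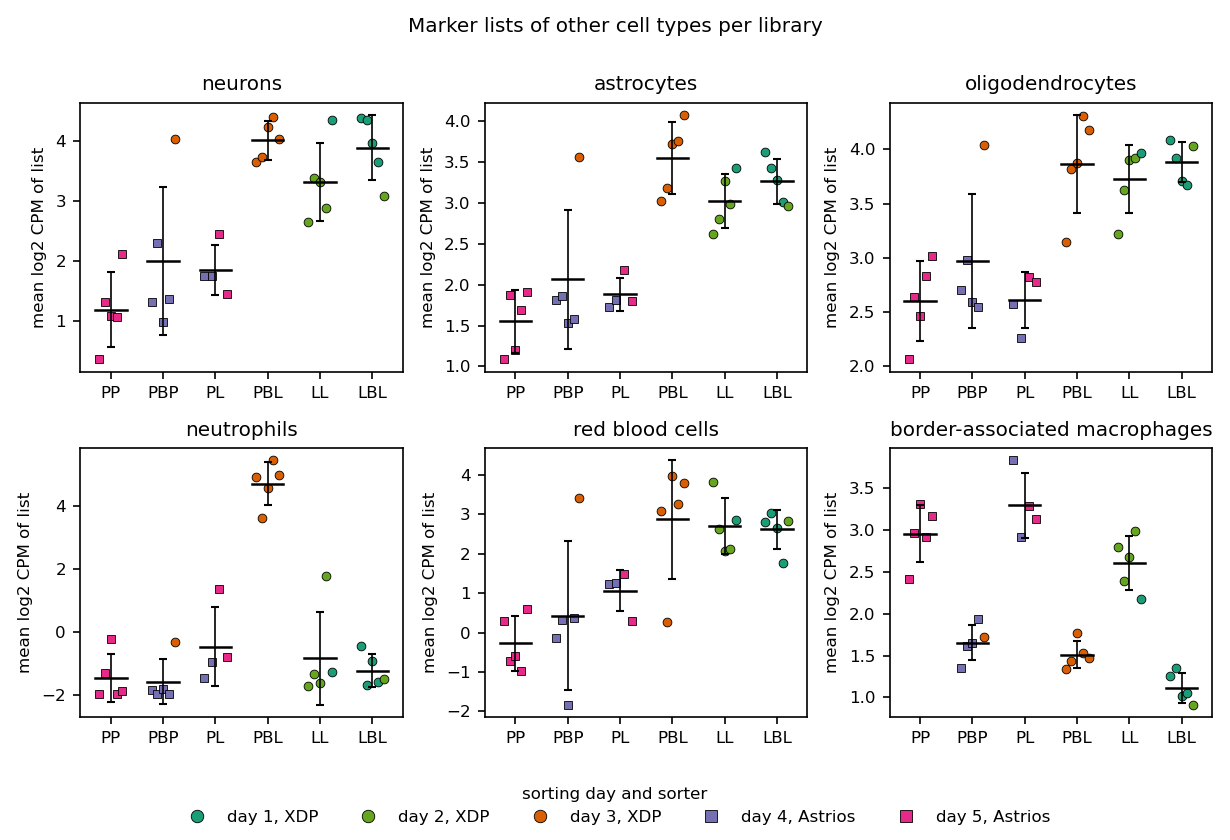
Mean log2 CPM of neuron, astrocyte, oligodendrocyte, neutrophil, red blood cell and border-associated macrophage markers (vertical axes) in each of the 29 libraries, by group (horizontal axes). Colours mark sorting days, circles the XDP and squares the Astrios, and bars the group mean ± SD.

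How do microglia respond to LPS when neither earlier LPS nor depletion came before (PL against PP)? Il1b, which encodes the cytokine interleukin 1 beta (ENSMUSG00000027398, chromosome 2), was at 1.87 ± 1.11 CPM in PP (SD, n = 5) and 292 ± 152 CPM in PL (n = 4), a log2 fold change of 7.28 (SE 0.53, adjusted p = 4.04e-11). Tnf, the gene of tumour necrosis factor (ENSMUSG00000024401, chromosome 17), went from 2.86 ± 1.42 to 147 ± 65.9 CPM (log2 fold change 5.68, SE 0.44, adjusted p = 9.56e-11). Cxcl10, a chemokine gene that interferons induce (ENSMUSG00000034855, chromosome 5), went from 1.56 ± 0.509 to 391 ± 219 CPM (7.95, SE 0.72, adjusted p = 3.94e-09). Responses differed between PL mice, from 70.6 to 398 CPM for Il1b. All 21 measured cytokine and chemokine genes rose, also when adjusted over the list alone (21), among them Ccl12 (5.59, SE 0.27), Ccl2 (4.02, SE 0.45), Osm (2.42, SE 0.17) and Il6 (1.40, SE 0.15).

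Of 29 measured NF-kB targets and feedback regulators, 26 rose, 1 fell and 2 did neither (27 and 1 adjusted over the list alone). Nfkbia, whose product holds NF-kB in the cytoplasm (ENSMUSG00000021025, chromosome 12), went from 158 ± 6.61 to 1818 ± 388 CPM (3.52, SE 0.12). Bcl3 rose by 6.70 (SE 0.25) and Socs3, a brake on cytokine signalling, by 6.5 (SE 0.22), while Marcks fell (-0.56, SE 0.10). Among interferon-stimulated genes 25 of 32 rose and none fell (28 adjusted over the list alone), such as Slfn2 (3.87, SE 0.16), Ifit1 (3.99, SE 0.30) and Gbp7 (1.75, SE 0.14). In the TLR4 pathway 9 of 20 genes rose, 3 fell and 8 did neither (9 and 3 over the list alone). Map3k8 (4.84, SE 0.22), the co-receptor gene Cd14 (2.01, SE 0.13) and the adaptor gene Myd88 (1.98, SE 0.14) rose. The receptor gene Tlr4 itself fell (-1.06, SE 0.15). Several genes were absent from every PP library and appeared with LPS. Il12b rose at least 745-fold, Trem1 at least 331-fold, Sphk1 at least 214-fold and Clec4e at least 177-fold.

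Genes of resting microglia went down with LPS. Sall1, a transcription factor gene of microglial identity (ENSMUSG00000031665, chromosome 8), fell from 448 ± 33.4 CPM in PP (SD, n = 5) to 100 ± 25.3 CPM in PL (n = 4; -2.16, SE 0.18, adjusted p = 9.03e-12). Gpr34 (-1.27, SE 0.13), the fractalkine receptor gene Cx3cr1 (-1.06, SE 0.12) and Tmem119 (-0.54, SE 0.12) fell too. The purine receptor gene P2ry12 (ENSMUSG00000036353, chromosome 3) fell from 11431 ± 1075 to 6222 ± 959 CPM (-0.88, SE 0.12). No change was called for Csf1r (-0.27, SE 0.13, adjusted p = 0.134). In all, 15 of 26 homeostatic genes fell and none rose (15 adjusted over the list alone). The deepest falls were in Cbx8 (-3.94, SE 0.41), Otud1 (-3.33, SE 0.38), Rgs2 (-3.21, SE 0.22) and Hhex (-2.96, SE 0.24). Of genes linked to microglia in disease, Fabp5 (5.59, SE 0.52), the cholesterol hydroxylase gene Ch25h (5.74, SE 0.56) and Spp1 (3.81, SE 0.44) rose and Clec7a fell (-1, SE 0.24). Of 21 glycolysis genes and HIF1A targets 4 rose, Slc2a1 (2.35, SE 0.15), Pfkfb3 (2.29, SE 0.16) and Ldha (1.39, SE 0.11) among them, and 5 fell, without a call for the list (adjusted p = 0.298).

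The list tests called cytokines (adjusted p = 2.47e-33), NF-kB targets (2.12e-41), interferon-stimulated genes (5.66e-20), TLR4 signalling (7.82e-06), complement and Fc receptors (8 of 16 higher, 8 over the list alone; 2.49e-05) and immediate early genes (11 of 16 higher, 12 over the list alone; 7.82e-06) upward. Homeostatic genes (4.22e-08) and the 2 measured lymphocyte genes, Ighm (-1.40, SE 0.14) and Cd79b (-1.09, SE 0.18), were called downward (0.000871). With an estimated correlation 2 of these calls were lost, homeostatic genes (adjusted p = 0.0882 with an estimated correlation) and complement (adjusted p = 0.0795 with an estimated correlation). No call was made for disease-associated genes (8 higher and 2 lower of 25; adjusted p = 0.0816), MHC class I (0.83) and class II (0.648), cell cycle (0.524), oxidative phosphorylation (0.83) or cholesterol synthesis (4 higher of 19; 0.121). Among the other lists of cell markers none was called: monocytes (0.189), border-associated macrophages (0.783), neutrophils (0.497), astrocytes (0.524), oligodendrocytes (0.83), neurons (0.497), endothelial cells (0.923) and red blood cells (0.516). Scores were not called for monocytes (0.8 higher, exact permutation adjusted p = 0.0793) or red blood cells (1.34 higher, 0.0992). Lymphocytes were lower by 1.24 (0.0397). For glycolysis, oxidative phosphorylation, oligodendrocyte and endothelial genes, the median, the mean and the test differed in sign.

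In all, 2369 genes rose and 1981 fell between PP (n = 5) and PL (n = 4), of which 1181 and 797 changed at least 2-fold. All PP libraries but only PL replicates 3 and 4 came from day 5. Within day 5, 2096 genes rose and 1522 fell, so the response did not need the change of day.

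**Figure D2:**
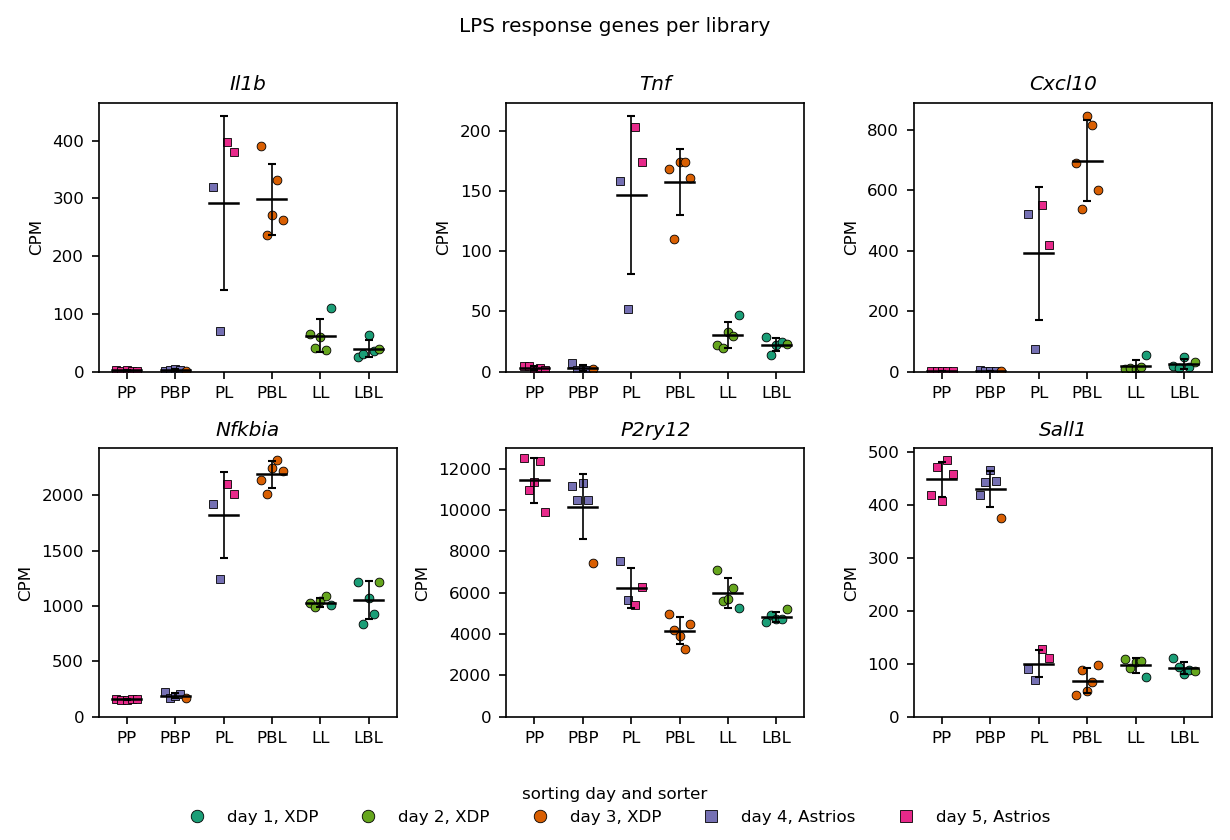
CPM on a linear scale (vertical axes) of Il1b, Tnf, Cxcl10, Nfkbia, P2ry12 and Sall1 in each library, by group (horizontal axes). Colours mark sorting days, circles the XDP and squares the Astrios, and bars the group mean ± SD.

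Do microglia that repopulated the brain respond to LPS (PBL against PBP, n = 5 each)? Il1b went from 2.29 ± 1.31 CPM in PBP (SD) to 298 ± 62.0 CPM in PBL (7.01, SE 0.51, adjusted p = 2.96e-11). Tnf went from 2.82 ± 2.46 to 158 ± 27.2 CPM (5.77, SE 0.43, adjusted p = 3.54e-11) and Cxcl10 from 2.25 ± 1.00 to 698 ± 134 CPM (8.26, SE 0.69, adjusted p = 7.79e-10). All 21 cytokine genes rose (21 over the list alone), with Ccl12 at 5.53 (SE 0.27) and Il6 at 1.41 (SE 0.14). NF-kB targets rose in 26 of 29 cases and fell in 1 (26 and 1 over the list alone), among them Nfkbia (3.51, SE 0.12), Bcl3 (6.57, SE 0.23) and Socs3 (6.60, SE 0.22). Of the interferon-stimulated genes 25 of 32 rose (27 over the list alone), among them Slfn2 (3.89, SE 0.15), Stat2 (2.34, SE 0.16), Trim30a (1.62, SE 0.11) and Ifit1 (2.87, SE 0.28). Sall1 fell from 429 ± 34.0 to 68.3 ± 24.3 CPM (-2.65, SE 0.17, adjusted p = 8.33e-15). Gpr34 (-1.62, SE 0.12), Mef2c (-1.13, SE 0.09), P2ry12 (-1.29, SE 0.11) and Tmem119 (-0.67, SE 0.11) fell too, of which Tmem119 lost its call with the sorter in the fit (-0.36, adjusted p = 0.186). In all 20 of 26 homeostatic genes fell (20 over the list alone). Tlr4 fell (-1.70, SE 0.15), as did Cbx8 (-3.98, SE 0.38), the receptor gene Lpar5 (-3.70, SE 0.34) and Rgs2 (-3.59, SE 0.20).

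Genes typical of cells other than microglia were higher in PBL. Whether they came from such cells, which the sorting gate is meant to leave out, or were induced in the sorted cells was not tested. Camp, which encodes a granule peptide of neutrophils (ENSMUSG00000038357, chromosome 9), was at 0.124 CPM in PBP and 50.7 ± 26.6 CPM in PBL (SD, n = 5). S100a9 (ENSMUSG00000056071, chromosome 3) was at 0.155 and 39.3 ± 19.6 CPM, and Lcn2 rose at least 169-fold. All 7 neutrophil genes rose (7 over the list alone; adjusted p = 0.0135; adjusted p = 0.408 with an estimated correlation). The neutrophil score rose by 6.28 (exact permutation p = 0.00794). Astrocyte (9 of 12, 10 over the list alone) and neuron genes (9 of 11, 10 over the list alone) were called higher too, each at adjusted p = 0.0135 (adjusted p = 0.379 and adjusted p = 0.566 with an estimated correlation), such as the neuron gene Camk2a (1.74, SE 0.47). Score differences were 2 for neurons and 1.48 for astrocytes (exact permutation p = 0.0238 each), 0.89 for oligodendrocytes (0.0397), and 1.09 for endothelial cells and 0.98 for monocytes (0.00794 each). The sorter in the fit ended the calls for neutrophils (adjusted p = 0.0594), astrocytes (0.724) and neurons (0.999). Camk2a came to 0.20 (adjusted p = 0.901), whereas Camp (6.32, adjusted p = 0.0679) and S100a9 (5.63, 0.0573) lost the call with fitted values still large, and Lcn2 stayed called (0.00517).

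Between PBP and PBL 3580 genes rose and 3583 fell (2238 and 1242 at least 2-fold). PBP replicates 1 to 4 were sorted on day 4 on the Astrios, PBL on day 3 on the XDP. Only PBP replicate 5 shared day and sorter with PBL. With the sorter in the fit the counts were 1230 and 994, among the XDP libraries alone 1218 and 839. Both compare PBL with PBP replicate 5 alone, with the spread taken from the other groups, and that library cannot show how PBP mice vary. The list tests called cytokines (6.72e-25), NF-kB targets (1.2e-32), interferon-stimulated genes (9.87e-14), TLR4 signalling (11 of 20 higher and 6 lower, 11 and 6 over the list alone; 0.00518), complement (9 of 16 higher and 1 lower, 9 and 1 over the list alone; 0.00904) and immediate early genes (8 of 16 higher and 2 lower, 8 and 3 over the list alone; 0.021) upward. Homeostatic genes (1.48e-10) and the 2 lymphocyte genes (both lower; 0.00244) were called downward. Calls were lost for homeostatic genes (adjusted p = 0.0622 with an estimated correlation), TLR4 signalling (adjusted p = 0.0999 with an estimated correlation), complement and immediate early genes (adjusted p = 0.356 with an estimated correlation for each). The median, the mean and the test differed in sign for MHC class I and glycolysis genes.

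Did depletion change the response to LPS itself (PBL minus PBP, compared with PL minus PP)? The differences between the 2 responses were -0.27 (SE 0.75) for Il1b, 0.09 (SE 0.62) for Tnf, 0.31 (SE 1.07) for Cxcl10, -0.01 (SE 0.16) for Nfkbia, -0.41 (SE 0.16) for P2ry12 and -0.64 (SE 0.21) for Tlr4, with adjusted p from 0.218 to 0.987. No gene was called: 2120 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.0533. With limma voom 69 genes were called higher and 131 lower, with DESeq2 21 and 45, and without PBP replicate 5, the library sorted with PBL, 310 and 430. The 2 LPS responses share no library. In both, 1863 genes rose (510 expected) and 1553 fell (427 expected). The Pearson correlation across genes, not independent replicates, was 0.749. List tests on the difference gave adjusted p = 0.987 for cytokines, 0.43 for interferon-stimulated genes and 0.487 for NF-kB targets. Neutrophil (0.00413), astrocyte (0.002) and neuron genes (0.00291) were called toward a larger rise with depletion. Homeostatic (0.00778), MHC class II (0.00702) and immediate early genes (0.00931) were called toward a lower value. No member of these lists was called over all genes. With an estimated correlation none of the 6 lists kept its call (smallest adjusted p = 0.425 with an estimated correlation). With the sorter in the fit the neuron genes turned direction (adjusted p = 0.0384).

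Does LPS given 5 weeks earlier change the response to a second LPS in mice that kept their microglia (LL against PL)? Il1b was at 292 ± 152 CPM in PL (SD, n = 4) and 62.4 ± 29 CPM in LL (n = 5), a log2 fold change of -2.23 (SE 0.39, adjusted p = 0.000794). Tnf went from 147 ± 65.9 to 30.2 ± 10.8 CPM (-2.29, SE 0.36, adjusted p = 0.000193) and Cxcl10 from 391 ± 219 to 19.0 ± 19.7 CPM (-4.35, SE 0.56, adjusted p = 2.75e-05). Of the 21 cytokine genes 19 fell and none rose (21 lower adjusted over the list alone), among them the neutrophil attractants Cxcl1 (-7.04, SE 0.97) and Cxcl2 (-4.34, SE 0.69), Cxcl9 (-3.14, SE 0.68) and Tnfsf9 (-3.09, SE 0.41). For Ccl2 no change was called (-0.82, SE 0.40, adjusted p = 0.317). The colony-stimulating factor gene Csf3, present in PL, had no count in LL and was lower by at least 66.4-fold.

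Regulators downstream of the receptor were lower too. NF-kB targets fell in 21 of 29 cases and none rose (29 lower over the list alone). Tnfaip3, which encodes a deubiquitinase that ends NF-kB signalling (-3.11, SE 0.36), Nfkbie (-1.96, SE 0.25) and Icam1 (-1.06, SE 0.13) were among them. Nfkbia fell from 1818 ± 388 CPM in PL (SD, n = 4) to 1030 ± 37.5 CPM in LL (n = 5; -0.82, SE 0.11). Of the interferon-stimulated genes 16 of 32 fell and none rose (23 over the list alone). Ifit1 went from 65.3 ± 19.8 to 10.6 ± 4.09 CPM (-2.63, SE 0.28, adjusted p = 1e-06) and Isg15 fell (-1.54, SE 0.22). MHC class II genes fell in 4 of 12 cases (6 over the list alone). Cd74 went from 747 ± 129 to 257 ± 107 CPM (-1.54, SE 0.23), and H2-Aa (-1.67, SE 0.33) and H2-Ab1 (-1.42, SE 0.26) fell. Lower as well were the NADPH oxidase gene Cybb (-1.77, SE 0.29), the peptide transporter gene Tap1 (-1.01, SE 0.16), Tlr2 (-2.06, SE 0.29), Cd14 (-0.89, SE 0.13), Cd40 (-3.18, SE 0.51), Gadd45b (-4.17, SE 0.54), Rnd1 (-3.27, SE 0.39) and Ch25h (-2.30, SE 0.41). No change was called for the resting genes P2ry12 (-0.06, SE 0.11), Tmem119 (-0.18, SE 0.11) and Sall1 (-0.05, SE 0.17) or for Tlr4 (0.38, SE 0.15), with adjusted p from 0.196 to 0.924. Of 26 homeostatic genes 1 was higher (1 over the list alone, list test adjusted p = 0.463).

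The list tests called cytokines (adjusted p = 8.55e-48), interferon-stimulated genes (3.77e-34), NF-kB targets (2.21e-52), TLR4 signalling (3 of 20 lower, 6 over the list alone; 5.14e-05), disease-associated genes (2 of 25 lower, 6 over the list alone; 3.49e-08), MHC class I (4 of 18 lower, 4 over the list alone; 7.13e-06), MHC class II (2.29e-09) and border-associated macrophage genes (none called, 1 lower over the list alone; 0.000976) downward. Also downward were complement (1 of 16 lower, 3 over the list alone; 0.00843), glycolysis (2 of 21, 4 over the list alone; 0.00145), cholesterol (1 of 19, 1 over the list alone; 0.0285) and immediate early genes (1 of 16, 4 over the list alone; 0.00059). All 4 lost the call: complement (adjusted p = 0.207 with an estimated correlation), glycolysis (adjusted p = 0.0662 with an estimated correlation), cholesterol (adjusted p = 0.139 with an estimated correlation) and immediate early genes (adjusted p = 0.0674 with an estimated correlation). Markers of other brain cells were higher in LL: neurons (3 of 11, 9 over the list alone; 1.38e-07; adjusted p = 0.0946 with an estimated correlation), astrocytes (3 of 12, 6 over the list alone; 3.04e-05; adjusted p = 0.0662 with an estimated correlation), oligodendrocytes (none over all genes, 6 of 12 over the list alone; 0.000358) and red blood cells (none; 0.00844; adjusted p = 0.207 with an estimated correlation). The scores were higher by 1.46 for neurons and 1.12 for oligodendrocytes (exact two-sided permutation p = 0.0159 each) and by 1.14 for astrocytes and 1.63 for red blood cells (0.00794 each). The score was lower by 0.69 for border-associated macrophages (0.0238). For neutrophil genes the median, the mean and the test differed in sign.

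Between PL (n = 4, Astrios, days 4 and 5) and LL (n = 5, XDP, days 1 and 2) 125 genes were higher and 338 lower (95 and 160 at least 2-fold). No sorting day or sorter held both groups, so that earlier LPS cannot be told apart from sorting day, nor over all genes from the sorter. The cytokine score was no lower in PBL, sorted on the XDP, than in PL (a difference of 0.12, SE 0.39), against -2.27 (SE 0.40) between LL and PL. With the sorter in the fit, a term that rests on PBP alone, 1 gene was called higher and 10 lower, and Adm alone of 37 named calls stayed. Il1b came to -0.17 (adjusted p = 0.987), Tnf to -2.04 (0.49), Cxcl10 to -3.37 (0.635), Nfkbia to -0.63 (0.218) and Ifit1 to -2.13 (0.139). Ch25h turned direction (4.58, adjusted p = 0.728). The lists of cytokines (1.5e-05), interferon-stimulated genes (8.43e-05) and NF-kB targets (1.38e-08) stayed called lower in that fit at the preset correlation, and all 3 lost the call there with an estimated one (adjusted p = 0.378 with an estimated correlation for each). MHC class II (0.938) and the other downward lists did not stay called. The neuron and red blood cell lists turned direction (0.0114 and 0.00821; adjusted p = 0.436 and adjusted p = 0.378 with an estimated correlation). The neuron score in the fit ended the calls of astrocyte (0.226), neuron (0.754) and red blood cell genes (0.499). The higher count came to 55 and 49 without PL replicate 1 or 4, and 69 and 71 without LL replicate 3 or 5. The lower count came to 221 and 223 without PL replicate 1 or 3. With limma voom the higher count was 54, with DESeq2 275, with the RNA quality number in the fit 217 and with the neuron score in the fit 34 (lower 204).

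Is the dampened response still there when the microglia present at the earlier LPS were depleted and replaced (LBL against PBL, n = 5 each, both sorted on the XDP)? Il1b was at 298 ± 62.0 CPM in PBL (SD) and 39.3 ± 14.6 CPM in LBL, a log2 fold change of -2.93 (SE 0.39, adjusted p = 1.47e-05). Tnf went from 158 ± 27.2 to 22.4 ± 5.50 CPM (-2.82, SE 0.35, adjusted p = 5.85e-06) and Cxcl10 from 698 ± 134 to 25.1 ± 15.6 CPM (-4.82, SE 0.56, adjusted p = 2.66e-06). Nfkbia went from 2187 ± 119 to 1054 ± 171 CPM (-1.05, SE 0.11, adjusted p = 9.12e-08). The libraries of the 2 groups did not overlap for any of these genes. Of the 21 cytokine genes 20 fell and none rose (21 over the list alone), with Ccl5 (-3.37, SE 0.38), Tnfsf9 (-3.42, SE 0.40) and Il6 (-0.95, SE 0.14). For Ccl2 no change was called (-0.80, SE 0.38, adjusted p = 0.244). NF-kB targets fell in 24 of 29 cases (29 over the list alone), with Icam1 (-1.27, SE 0.13) and Tnip1 (-1.71, SE 0.19). Of 32 interferon-stimulated genes 18 fell (26 over the list alone). Ifit1 went from 51.9 ± 15.2 to 12.5 ± 2.96 CPM (-2.05, SE 0.27), and Isg15 (-1.73, SE 0.21) and Gbp2 (-1.92, SE 0.27) fell.

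Of the receptors upstream, Tlr2 (-2.12, SE 0.28) and Cd14 (-0.76, SE 0.12) were lower in LBL. Tlr4 was higher, 51.3 ± 7.55 CPM in PBL (SD, n = 5) and 95 ± 5.72 CPM in LBL (n = 5; 0.89, SE 0.15, adjusted p = 9.36e-05). Cd74 (-1.06, SE 0.22), Cybb (-1.77, SE 0.28) and Ch25h (-2.38, SE 0.37) fell. Rises in LBL were smaller in size, such as Klhl6 (1.28, SE 0.17), Zbtb14 (1.42, SE 0.24), the potassium channel gene Kcnj2 (1.29, SE 0.27) and the purine receptor gene P2ry13 (0.46, SE 0.11). No change was called for P2ry12 (0.21, SE 0.11, adjusted p = 0.278) or Tmem119 (0.07, SE 0.11, adjusted p = 0.81). Among the deepest falls were neutrophil genes. Camp, absent from LBL, was lower by at least 653-fold, and S100a9 (-8.69, SE 1.19), Ltf (-8.96, SE 1.37), Ngp (-8.54, SE 1.35) and S100a8 (-7.02, SE 1.09) fell with it. Chil3, a gene of the monocyte list also absent from LBL, was lower by at least 384-fold, and Anxa1 fell as well (-5.82, SE 0.99).

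The list tests called cytokines (adjusted p = 5.22e-43), interferon-stimulated genes (1.67e-23), NF-kB targets (1.77e-60) and neutrophils (7 of 7 lower, 7 over the list alone; 5.08e-08) downward. Called downward but lost with an estimated correlation were TLR4 signalling (1 of 20 higher and 5 lower, 3 and 7 over the list alone; 0.0313; adjusted p = 0.344 with an estimated correlation), disease-associated genes (2 of 25 lower, 2 over the list alone; 0.0111; adjusted p = 0.427 with an estimated correlation) and MHC class I (3 of 18 lower, 4 over the list alone; 0.0336; adjusted p = 0.427 with an estimated correlation). So were immediate early genes (3 of 16 lower, 1 higher and 6 lower over the list alone; 0.0313; adjusted p = 0.344 with an estimated correlation) and monocytes (3 of 13 lower, 3 over the list alone; 0.0403; adjusted p = 0.344 with an estimated correlation). Homeostatic genes were called upward (2 of 26 higher, 2 over the list alone; 0.00824; adjusted p = 0.427 with an estimated correlation). MHC class II was not called (2 of 12 lower; 0.0697). The neutrophil score was lower by 5.93 and the monocyte score by 0.9 (exact two-sided permutation p = 0.00794 each), and the border-associated macrophage score by 0.39 (0.0159). The neuron score differed by -0.12 (0.698) and the astrocyte score by -0.29 (0.246). For glycolysis, oligodendrocyte and endothelial genes the median, the mean and the test differed in sign.

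Between PBL and LBL 456 genes were higher and 665 lower (71 and 282 at least 2-fold). PBL was sorted on day 3 and LBL on days 1 and 2, so that earlier LPS cannot be told apart from sorting day. The higher count came to 232 without PBL replicate 4, and 253 and 257 without LBL replicate 2 or 4. The lower count came to 416 without LBL replicate 2. With limma voom 725 genes were higher and 1123 lower, and with the RNA quality number in the fit 196 and 442.

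Does depletion change what the earlier LPS left behind (LBL minus PBL, compared with LL minus PL)? The differences between the 2 effects were -0.70 (SE 0.53) for Il1b, -0.53 (SE 0.49) for Tnf, -0.47 (SE 0.72) for Cxcl10, -0.23 (SE 0.16) for Nfkbia and 0.51 (SE 0.21) for Tlr4, with adjusted p from 0.275 to 0.796. The list tests gave adjusted p = 0.635 for cytokines, 0.345 for interferon-stimulated genes and 0.0643 for NF-kB targets. No loss of the dampened response with depletion was called, and response genes pointed either way, as Ifit1 (0.58, SE 0.38) and Irf7 (1.05, SE 0.44) pointed toward less dampening. The 2 effects share no library. In both, 242 genes were lower (13.5 expected) and 11 were higher (3.43 expected). Of the genes called lower in LL against PL 97% had the same sign in LBL against PBL, and of those called higher 56.8%. Across all genes, not independent replicates, the Pearson correlation was 0.189.

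Between these 2 effects, 2 genes were called higher and 2 lower, at a smallest adjusted p of 0.0495, and 2417 genes had an unadjusted p under 0.05. Limma voom called 11 higher and 28 lower and DESeq2 25 and 27. Called higher were the transcription factor gene Max (ENSMUSG00000059436, chromosome 12; 0.97, SE 0.19) and Tnfrsf11a, the gene of RANK (ENSMUSG00000026321, chromosome 1; 0.90, SE 0.17). Lower were Atp1b2, a sodium pump subunit gene of astrocytes (ENSMUSG00000041329, chromosome 11; -4.25, SE 0.74), and Serpinb1a, a protease inhibitor gene of neutrophils (ENSMUSG00000044734, chromosome 13). Serpinb1a, named after its values were seen, had no count in PL and was at 2.74 ± 1.67 CPM in PBL (SD, n = 5). Each of these calls ended when 1 of several libraries was left out and with the sorter in the fit (adjusted p = 0.954). Without PL replicate 3 there were 11 genes higher and 12 lower, and without any other library at most 2 and 4. Neuron (1.22e-05; 5 lower over the list alone), astrocyte (1.5e-05; 3 lower), neutrophil (3.72e-05; 6 lower), oligodendrocyte (0.0123) and red blood cell genes (0.0175) were called toward a lower value with depletion. Homeostatic (0.00512), MHC class II (0.00569) and glycolysis genes (0.0175) were called toward a higher one. No member of the 8 lists was called over all genes. With an estimated correlation none of the 8 lists kept its call (adjusted p = 0.253 with an estimated correlation for the smallest). Neuron and red blood cell genes with the sorter in the fit turned direction (adjusted p = 0.0107 each).

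**Figure D3:**
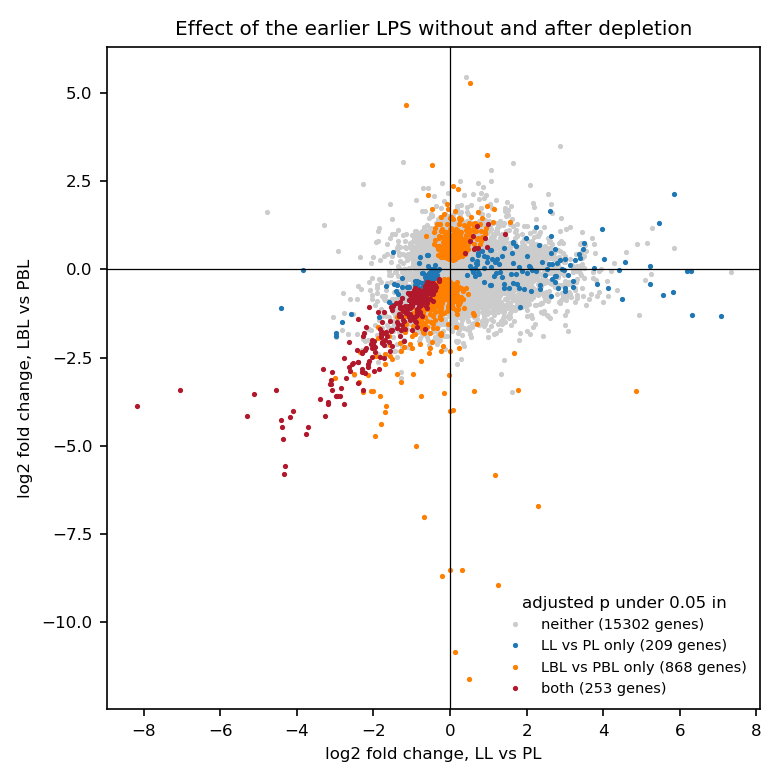
Log2 fold change of each tested gene after earlier LPS without depletion (LL against PL, horizontal axis) and with depletion (LBL against PBL, vertical axis). Grey genes were called in neither (15302), blue in LL against PL only (209), orange in LBL against PBL only (868) and red in both (253).

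Genes induced by LPS in the mice without depletion (1181 genes, PL against PP) were traced in the depleted mice, which share no library with them. After earlier LPS 321 of them were lower and 8 higher in LBL than in PBL. Their median log2 fold change was -0.41, 79.6% were below 0, and the list test called them lower (adjusted p = 6.76e-35). Of the 797 genes that LPS lowered, 84 were higher and 4 lower in LBL (adjusted p = 1.74e-09). Conversely, the 2238 genes induced in depleted mice (PBL against PBP) were less uniform in LL against PL. Of these 220 were lower and 51 higher (median 0.09), and the test pointed downward without a call (adjusted p = 0.278). That list held genes of neurons and other cells. Without PBP replicate 5 (median 0.37) or PL replicate 3 (0.23) the test pointed upward, without any other library downward (unadjusted p 0.000324 to 0.837). Of the 1242 genes lowered in depleted mice, 22 were higher and none lower in LL (adjusted p = 0.00203; adjusted p = 0.216 with an estimated correlation).

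How much of the LPS response was left after earlier LPS? Against PP (n = 5), LL (n = 5) had 3145 genes higher and 2195 lower, and 1566 of the 2238 genes induced in depleted mice (70%) were higher. Against PBP, LBL (n = 5 each) had 2423 higher and 2261 lower, and 894 of the 1181 genes induced without depletion (75.7%) were higher. LL and PP share no sorter or sorting day, and LBL shares only the sorter, and only with PBP replicate 5, so that LPS cannot be told apart from them in these counts. The neuron score was 3.31 in LL and 1.19 in PP, 3.88 in LBL and 2 in PBP. In LL 15 of 21 cytokine genes were above PP (15 over the list alone; adjusted p = 3.27e-11; adjusted p = 0.102 with an estimated correlation) and in LBL 15 above PBP (15 over the list alone; 9.85e-11; adjusted p = 0.125 with an estimated correlation). NF-kB targets were higher in 20 and lower in 2 of 29 cases in LL (5.09e-14; adjusted p = 0.0875 with an estimated correlation) and in 16 and 2 in LBL (1.6e-11; adjusted p = 0.111 with an estimated correlation). Homeostatic genes were lower in 16 of 26 cases in LL (1.23e-10; adjusted p = 0.0937 with an estimated correlation) and in 15 in LBL (2.71e-10; adjusted p = 0.111 with an estimated correlation). Interferon-stimulated genes were higher in 12 of 32 cases in LL (0.000339; adjusted p = 0.277 with an estimated correlation) and in 12 with 2 lower in LBL (0.000185; adjusted p = 0.364 with an estimated correlation). With the sorter in the fit the counts were 796 and 385 for LL and 945 and 664 for LBL, and 17.4% and 28% of the calls were kept.

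What do repopulated microglia look like without any LPS (PBP against PP, n = 5 each)? Crybb1, a crystallin gene expressed in mature microglia (ENSMUSG00000029343, chromosome 5), fell from 373 ± 18.6 CPM in PP (SD) to 171 ± 8.53 CPM in PBP, a log2 fold change of -1.13 (SE 0.10, adjusted p = 2.81e-08). Pecam1 fell from 35.3 ± 3.56 to 11.4 ± 4.78 CPM (-1.62, SE 0.25). Fcrls (-0.56, SE 0.09), Slamf1 (-1.28, SE 0.18), Tmem44 (-1.72, SE 0.27), Abcg3 (-1.82, SE 0.39) and the B cell receptor gene Cd79b (-1.02, SE 0.17) fell with it. Axl, which encodes a receptor for dying cells (ENSMUSG00000002602, chromosome 7), rose from 11.2 ± 1.74 to 37.4 ± 8.68 CPM (1.74, SE 0.24, adjusted p = 8.31e-05). The hyaluronan receptor gene Cd44 (2.15, SE 0.40), Fabp5 (3.07, SE 0.56), Arhgap15 (1.60, SE 0.28), Hcar2 (1.32, SE 0.23) and the interferon-induced gene Ifi204 (1.15, SE 0.22) rose too. No difference from PP was called for P2ry12 (-0.17, SE 0.11), Tmem119 (0.11, SE 0.11), Sall1 (-0.06, SE 0.16) or Csf1r (0.02, SE 0.13), with adjusted p from 0.575 to 0.98. Among genes of dividing cells no change was called for Mki67 (-2.02, SE 0.74, adjusted p = 0.23) or Ccnb2 (-2.28, SE 0.58, adjusted p = 0.061), though Ccnb2 was called lower with the sorter in the fit (adjusted p = 0.0214).

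Markers of border-associated macrophages, the macrophages of meninges and perivascular spaces, were lower in PBP. Mrc1, the mannose receptor gene (ENSMUSG00000026712, chromosome 2), was at 33.5 ± 8.23 CPM in PP (SD, n = 5) and 14.6 ± 3.98 CPM in PBP (n = 5; -1.19, SE 0.27, adjusted p = 0.0277). The call ended without PP replicate 2 (0.0576), 3 (0.0824), 4 (0.0618) or 5 (0.0544) and without PBP replicate 1 (0.066), 3 (0.0589) or 5 (0.0726), and with the sorter in the fit (0.072). Cd209f was lower (-2.99, SE 0.62, adjusted p = 0.0117; 0.0504 without PBP replicate 2). Cbr2 was not called (-1.46, SE 0.37, adjusted p = 0.059). Over the list, 2 of 12 genes were lower (10 over the list alone; adjusted p = 2.13e-14), and the score was lower by 1.3 (exact two-sided permutation p = 0.00794). That list stayed called with the sorter in the fit (1.67e-15), with sorting day in the fit (1.93e-06) and among Astrios libraries alone (1.38e-15).

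Called downward too were cell cycle genes (none of 27 over all genes, 1 lower over the list alone; 1.8e-05) and the 2 lymphocyte genes (1 lower, 2 over the list alone; 2.19e-06). Homeostatic (3 of 26 lower, 3 over the list alone; 0.000119; adjusted p = 0.432 with an estimated correlation) and oxidative phosphorylation genes (none; 3.1e-09; adjusted p = 0.22 with an estimated correlation) were called downward and lost the call. Upward and lost were interferon-stimulated (1 of 32 higher, 4 higher and 1 lower over the list alone; 0.000184; adjusted p = 0.432 with an estimated correlation), NF-kB (none; 0.0487; adjusted p = 0.663 with an estimated correlation) and neuron genes (1 of 11 higher, 4 over the list alone; 0.000119; adjusted p = 0.432 with an estimated correlation). The neuron score was higher by 0.81 (exact permutation p = 0.214), and the neuron call ended with the sorter in the fit (0.132). Sorting day in the fit ended the calls of lymphocyte (0.061), interferon-stimulated (0.0776), homeostatic (0.295) and oxidative phosphorylation genes (0.134). For complement and glycolysis genes the median, the mean and the test differed in sign. In all, 48 genes rose and 40 fell (34 and 19 at least 2-fold). There were 87 and 72 with limma voom, 192 and 101 with DESeq2, and 6 and 5 with sorting day in the fit, which left Axl and Tmem44 of 22 named calls. The counts came to 25 higher and 24 lower without PP replicate 1, 31 and 25 without PP replicate 3, and 25 and 25 without PBP replicate 2. PP was sorted on day 5 and PBP on days 4 and 3, and the counts among Astrios libraries alone were 38 and 28.

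**Figure D4:**
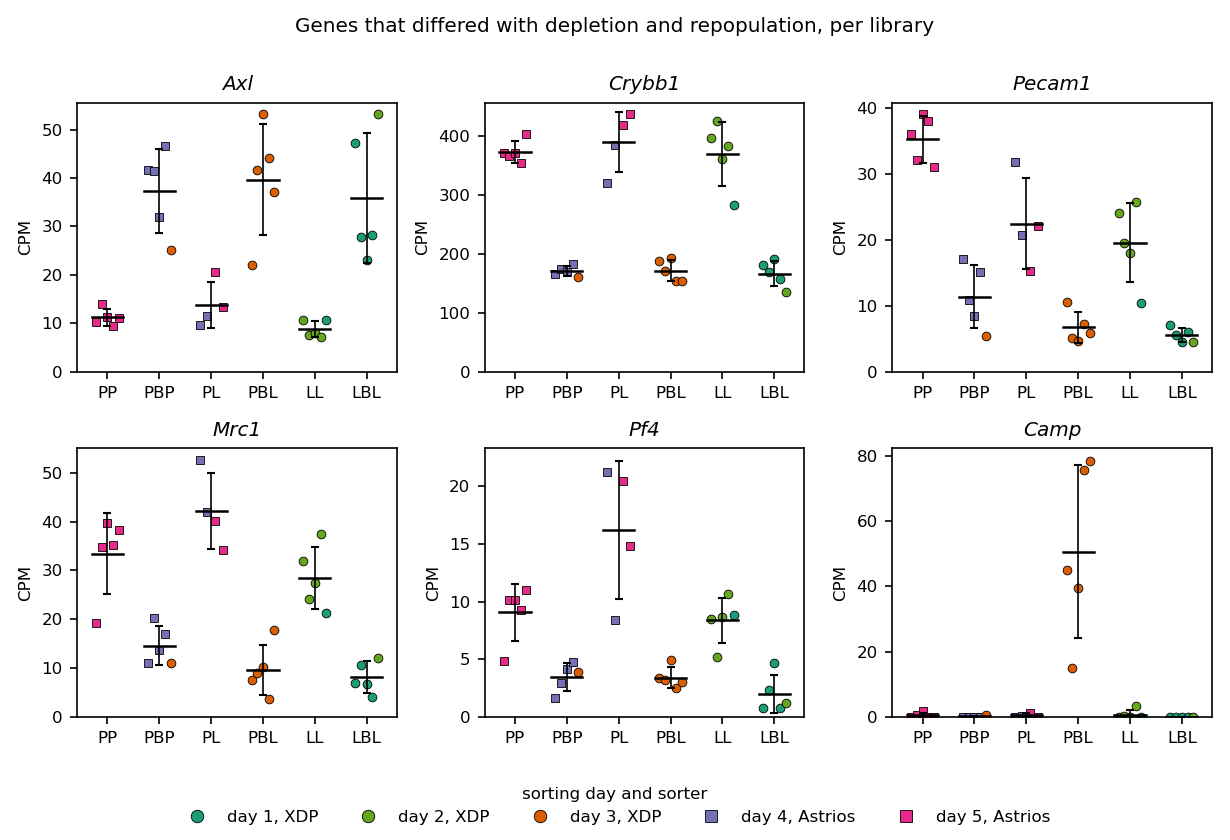
CPM on a linear scale (vertical axes) of Axl, Crybb1, Pecam1, Mrc1, Pf4 and Camp in each library, by group (horizontal axes). Colours mark sorting days, circles the XDP and squares the Astrios, and bars the group mean ± SD.

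Does depletion mark microglia in the LPS-challenged mice as well (PBL against PL, and LBL against LL)? LBL and LL (n = 5 each) shared the sorter but mostly not the day. In LBL Crybb1 fell from 370 ± 54.1 to 166 ± 21.8 CPM (SD, log2 -1.15, SE 0.10, adjusted p = 1.62e-08). Pecam1 fell from 19.6 ± 6.02 to 5.52 ± 1.1 CPM (-1.82, SE 0.27) and Mrc1 from 28.5 ± 6.41 to 8.11 ± 3.25 CPM (-1.80, SE 0.28). The platelet factor gene Pf4 (ENSMUSG00000029373, chromosome 5) fell from 8.37 ± 1.97 to 1.95 ± 1.64 CPM (-2.10, SE 0.38). F13a1 (-2.02, SE 0.38), Fcrls (-0.50, SE 0.09), Ecscr (-0.57, SE 0.10) and Cd79b (-1.44, SE 0.18) fell with them. Axl rose from 8.79 ± 1.71 to 35.9 ± 13.4 CPM (2.03, SE 0.24, adjusted p = 6.75e-06). Htra3 (2.27, SE 0.38), Pdcd1, the gene of the checkpoint receptor PD-1 (1.65, SE 0.23), Arhgap15 (1.54, SE 0.28) and Fn1 (2.01, SE 0.42) rose as well. So did Ch25h (2.00, SE 0.40), Tap1 (0.77, SE 0.15) and Lgals3bp (0.65, SE 0.12). No difference was called in the response genes Il1b (-0.67, SE 0.37), Tnf (-0.43, SE 0.35), Cxcl10 (0.36, SE 0.52) and Nfkbia (0.03, SE 0.11), with adjusted p from 0.477 to 0.94. None of 21 cytokine genes was called (list test 0.923).

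In LBL against LL, border-associated macrophage (7 of 12 lower, 8 over the list alone; adjusted p = 5.68e-17) and lymphocyte genes (1 of 2 lower, 2 over the list alone; 5.11e-08) were called downward and kept the call with an estimated correlation and with sorting day in the fit. The macrophage score was lower by 1.49 (exact permutation p = 0.00794), and the neuron score higher by 0.57 (0.159). Oxidative phosphorylation genes (3 of 39 lower, such as Ndufa2 at -0.54 (SE 0.11), 16 over the list alone; 2.44e-13), homeostatic (1 of 26 higher and 3 lower, 4 and 8 over the list alone; 0.00128) and cell cycle genes (none; 0.0419) were called downward and lost the call (adjusted p = 0.111, adjusted p = 0.514 and adjusted p = 0.111 with an estimated correlation). Interferon-stimulated (1 of 32 higher, 4 over the list alone; 0.000228), disease-associated (3 of 25 higher, 5 higher and 1 lower over the list alone; 0.0113), MHC class I (3 of 18 higher, 7 higher and 3 lower over the list alone; 0.0419) and neuron genes (none; 0.044) were called upward and lost it (adjusted p = 0.514 with an estimated correlation for the 3 immune lists, adjusted p = 0.889 with an estimated correlation for neurons). Sorting day in the fit ended the calls of homeostatic (0.501), cell cycle (0.0806) and neuron genes (0.651). For cytokine, complement and endothelial genes the median, the mean and the test differed in sign.

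Between LL and LBL 81 genes were higher and 120 lower (33 and 28 at least 2-fold). The higher count came to 53, 53 and 36 without LL replicate 1, 3 or 4. It came to 51, 52 and 42 without LBL replicate 1, 2 or 5. The lower count came to 60, 49, 77, 70 and 71 without LL replicate 1 or 4 or LBL replicate 1, 2 or 5. It was 210 with the sorter, 59 with sorting day, 207 with the RNA quality number and 76 with the neuron score in the fit. Limma voom called 256 higher and 300 lower and DESeq2 187 and 267. LBL replicates 1 to 4 and LL replicate 5 were sorted on day 1, the others on day 2. Day thus nearly coincided with depletion. With day in the fit 19 of 23 named calls stayed.

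In PBL (n = 5) against PL (n = 4), Crybb1 fell from 390 ± 50.9 to 171 ± 18.1 CPM (SD; -1.19, SE 0.11, adjusted p = 2.53e-08) and Mrc1 from 42.2 ± 7.71 to 9.62 ± 5.15 CPM (-2.12, SE 0.29). Pf4 (-2.26, SE 0.38), Cbr2 (-2.67, SE 0.42) and Pecam1 (-1.75, SE 0.28) fell too. Axl rose from 13.7 ± 4.83 to 39.6 ± 11.4 CPM (1.52, SE 0.25). Of 12 MHC class II genes 5 fell, such as H2-Aa (-1.84, SE 0.33), H2-Eb1 (-1.80, SE 0.33) and H2-Ab1 (-1.32, SE 0.26), and these 3 lost the call with the sorter in the fit (-0.9, -1 and -0.56; adjusted p = 0.894, 0.882 and 0.924). P2ry12 (-0.58, SE 0.11), Apoe (-0.68, SE 0.13) and the respiratory chain gene Ndufv1 (-0.65, SE 0.11) fell by less. No difference was called for Il1b (0.03, SE 0.37, adjusted p = 0.968) or Tnf (0.10, SE 0.34, adjusted p = 0.863). Il6 was higher (0.60, SE 0.14) and Ccl7 lower (-1.50, SE 0.36). Genes of other cells were far higher in PBL. Among them were the neutrophil genes Camp (6.82, SE 1.12), S100a9 (5.34, SE 0.98) and Ltf (5.93, SE 1.15), and Anxa1 rose too (7.98, SE 1.34). The neuron genes Snap25 (2.15, SE 0.45) and Camk2a (2.44, SE 0.54) rose, as did Clu (2.28, SE 0.40) of astrocytes, and Mbp (2.09, SE 0.41) and Mobp (2.94, SE 0.66) of oligodendrocytes. The scores were higher by 5.17 for neutrophils, 2.16 for neurons and 1.67 for astrocytes, and lower by 1.79 for border-associated macrophages (exact permutation p = 0.00794 each).

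Border-associated macrophage (7 of 12 lower, 10 over the list alone; adjusted p = 3.98e-08), cell cycle (4 of 27 lower, 2 over the list alone; 0.00625) and lymphocyte genes (2 lower, 2 over the list alone; 0.00183) were called downward in PBL against PL. Calls lost with an estimated correlation (adjusted p = 0.181 with an estimated correlation for each, 0.182 for neutrophils) were homeostatic (13 of 26 lower, 15 over the list alone; 1.63e-06), MHC class II (5 of 12 lower, 1 higher and 6 lower over the list alone; 0.00615) and oxidative phosphorylation genes (17 of 39 lower and 1 higher, 20 and 1 over the list alone; 3.66e-07) downward. Lost upward calls were neutrophil (7 of 7 higher, 7 over the list alone; 0.00144), neuron (11 of 11, 11 over the list alone; 3.66e-07), astrocyte (8 of 12 higher and 1 lower, 8 and 1 over the list alone; 4.83e-05) and oligodendrocyte genes (6 of 12 higher and 1 lower, 7 and 2 over the list alone; 0.0135). No call was made for cytokines (0.842), interferon-stimulated genes (4 of 32 higher; 0.171) or NF-kB targets (6 of 29 higher; 0.0512). For disease-associated, MHC class I and complement genes the median, the mean and the test differed in sign.

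In all, 1828 genes were higher and 1845 lower in PBL than in PL (1176 and 145 at least 2-fold). The groups shared neither sorter nor day, and PBL had the lowest RNA quality, so that depletion cannot be told apart from them here. With the sorter in the fit no gene was higher and 3 were lower, with sorting day 2 and 3, with the neuron score 4 and 9, and with the RNA quality number 1151 and 1146. Only Crybb1 of 32 named calls stayed with the sorter (-1.08, adjusted p = 0.0384). Axl came to 2.21 (0.185) and Mrc1 to -1.63 (0.706), and S100a9 turned direction (-0.28, adjusted p = 0.98). The border-associated macrophage list alone of 10 stayed called (2.14e-09). The counts came to 1060 higher without PL replicate 2 and 1125 without PBL replicate 4. They came to 1123 lower without PL replicate 1 and 1201 without PBL replicate 4. A fit on these 2 groups alone called 1107 genes lower.

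The mark of depletion was shared between challenges. PBP against PP and LBL against LL share no library. In both, 14 genes were higher (0.234 expected) and 21 lower (0.289 expected), Crybb1, Pecam1, Fcrls, Cd79b, Axl and Arhgap15 among them. The sign was the same for 97.9% and 97.5% of the called genes. The Pearson correlation across genes, not independent replicates, was 0.353. PBP against PP shared 33 higher and 29 lower genes with PBL against PL (5.28 and 4.44 expected; correlation 0.511). PBL and PL share no sorter or sorting day and PBP replicate 5 was sorted with PBL, so that in this overlap depletion cannot be told apart from them. PBL against PL shared 42 and 94 with LBL against LL (8.9 and 13.3 expected; correlation 0.382).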

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

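The tests of sorter, RNA quality, sorting day and depletion on the cytokine and the brain cell patterns, the sorter test on the macrophage markers and the check without Stab1 were chosen after the results were seen.

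Single libraries lay far from the others of their group in 7 of 72 groups tested over 12 measures, where chance gives about 1 in 20. PBP replicate 5 had an RNA quality number of 7.4 (others 8.8 to 9), an astrocyte score of 3.57 (1.53 to 1.86) and a neutrophil score of -0.302 (-1.95 to -1.8). PP replicate 1 had an immediate early gene score of 5.41 (4.35 to 4.65), LL replicate 4 a neutrophil score of 1.79 (-1.7 to -1.25), LBL replicate 1 an endothelial score of 2.19 (1.31 to 1.56) and PBL replicate 2 a red blood cell score of 0.269 (3.09 to 3.97).

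The effect of earlier LPS differed between mice with and without depletion for 4 genes: Atp1b2 (-4.25), Max (0.97), Tnfrsf11a (0.90) and Serpinb1a (-8.32, a fitted value with PL at 0 counts; this gene was named after its values were seen). It also differed for the lists of homeostatic (adjusted p = 0.00512), MHC class II (0.00569), glycolysis (0.0175), neutrophil (3.72e-05), astrocyte (1.5e-05), oligodendrocyte (0.0123), neuron (1.22e-05) and red blood cell genes (0.0175), of which none kept its call (smallest adjusted p = 0.253 with an estimated correlation). The response to LPS differed between mice with and without depletion for homeostatic (0.00778), MHC class II (0.00702), immediate early (0.00931), neutrophil (0.00413), astrocyte (0.002) and neuron genes (0.00291), of which none kept its call (smallest adjusted p = 0.425 with an estimated correlation).

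Cytokine genes were lower after earlier LPS in both arms. The sorter is excluded for LBL against PBL, where both groups came from the XDP and 20 of 21 genes were lower, and RNA quality is excluded, since 19 genes stayed lower in LBL against PBL and 19 in LL against PL with the RNA quality number in the fit. For LL against PL the sorter as the whole cause is argued against, if depletion acts alike after a first and a second LPS. The list score was no lower in PBL on the XDP than in PL on the Astrios (0.12, SE 0.39, against -2.27, SE 0.40, in LL against PL), and on 1 sorter depletion did not raise it by a like amount (-0.02, SE 0.23, in LBL against LL; 0.19, SE 0.17, in PBP without replicate 5 against PP). A sorter effect on a part of the fall, or one hidden by a rise with depletion after a first LPS only, stays open. With the sorter in the fit the list had p = 0.0986 with an estimated correlation, 19 of 21 genes stayed below 0 and none was called; the median log2 fold change went from -2.27 to -1.33 and the median of the single genes' SEs from 0.38 to 1.18. Sorting day cannot be excluded in either arm, because 0 days held libraries with and without earlier LPS. Sorting day or innate immune memory may explain the pattern. Whether the memory lies in microglia was not tested.

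Genes of neurons, astrocytes and oligodendrocytes were higher in PBL than in PL. The 1828 genes higher in PBL differed by a median of 1.46. PBP replicate 5, sorted with PBL but given no LPS, exceeded the other PBP libraries in these by a median of 1.05. Sorter, day or its low RNA quality (7.4) may be why, but 1 library cannot tell. Depletion as the whole cause in all arms is argued against, and a part stays open. The 3 scores' mean differed by 0.32 (SE 0.22, exact permutation p = 0.167) in LBL against LL. It differed by 0.18 (SE 0.25, 0.452) in PBP without replicate 5 against PP and 1.69 (SE 0.21, 0.00794) in PBL against PL.

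Markers of border-associated macrophages were lower after repopulation. The sorter is excluded, as the list stayed lower within each sorter (larger p = 2.56e-06 with an estimated correlation), and sorting day is excluded for LBL against LL (5.43e-05 with day in the fit). Fewer border-associated macrophages among the sorted cells, lowering all their markers by 1 factor, are argued against as the whole cause by a chi-square test of whether the markers fell alike (smallest p = 1.2e-25). Without Stab1, which was at 222.3 to 297.4 CPM in all groups, the p-values were 0.0305, 0.00334 and 0.00318. A loss of these cells beside RNA of the same genes from microglia, which lowers markers unequally, was not tested and stays open, as does a change in the microglia.

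Per comparison, 50 splits into the same group sizes were fitted on its libraries alone, so counts differ from the fit on all groups. In 9 comparisons the real split alone called as many genes (1 of 50, the lowest possible), so chance is argued against, not excluded. Real and highest other counts were 4086 and 1439 (PL against PP), 5935 and 2705 (PBL against PBP), 372 and 132 (LL against PL), 1300 and 417 (LBL against PBL), 63 and 0 (PBP against PP), 2867 and 0 (PBL against PL), 251 and 244 (LBL against LL), 4937 and 0 (LL against PP) and 3946 and 336 (LBL against PBP). The split with 244 in LBL against LL follows sorting day and shares 8 of 10 libraries with the depletion split, so its count mixes both; with day in the fit 99 genes were higher and 59 lower. For the earlier LPS by depletion difference 3 of 50 splits reached the real count of 35, the highest 541, so chance cannot be excluded and the samples carry a structure of their own. For the LPS by depletion difference 50 of 50 splits reached the real count of 0 (highest other 1).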

How the results depend on the processing

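Sorting day, RNA quality number and neuron score as covariates, the fits within day 5, the XDP or the Astrios, the list tests with the sorter and an estimated correlation, the LPS list from XDP libraries, the correlation over genes called in either comparison, the leave-one-out runs of LPS lists and correlations, and the RLE and leave-one-out runs of cell type scores were chosen after the results were seen.

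Of 232 called results for named genes, RLE kept 226, no filter 219, the replicate block 224, limma voom 223, DESeq2 230 of 231, fits on only the groups compared 222 of 227, the RNA quality number 226, the sorter 150, sorting day 97 of 163 and the neuron score 188; leaving out any 1 library kept 210. With the sorter 27 of 34 calls stayed in PBL against PBP, 18 of 22 in PBP against PP, 1 of 37 in LL against PL and 1 of 32 in PBL against PL. All calls stayed in PL against PP (48), LBL against PBL (32) and LBL against LL (23). There both groups came from 1 sorter, so the term could not change the folds and these kept calls test nothing. The cause of changes under the covariates was not tested beyond the weighing of technical causes; fewer libraries or fewer residual degrees of freedom lower the power of several.

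Counts of genes called, higher and lower, where an alternative moved them over 1.5 times: PBL against PBP 1230 and 994 (sorter), 1218 and 839 (XDP, with PBP replicate 5 alone), 1301 and 1078 (day), 1830 and 1657 (neuron score). LL against PL higher 77 (block), 1 (sorter), 54 (voom), 275 (DESeq2), 217 (RNA quality), 34 (neuron score); lower 10 (sorter), 204 (neuron score). LBL against PBL 725 and 1123 (voom), 196 and 442 (RNA quality). PBP against PP higher 31 (only the groups compared), 87 (voom), 192 (DESeq2), 6 (day); lower 72, 101, 5 and, with the neuron score, 24. PBL against PL higher 0 (sorter), 2 (day), 1151 (RNA quality), 4 (neuron score); lower 3, 3, 1146, 9 and, on only the groups compared, 1107. LBL against LL higher 256 (voom), 187 (DESeq2); lower 64 (no filter), 182 (block), 210 (sorter), 300 (voom), 267 (DESeq2), 59 (day), 207 (RNA quality), 76 (neuron score). LL against PP 796 and 385 (sorter), 1266 and 808 (neuron score); LBL against PBP 945 and 664, 1297 and 1007. The cause was not tested.

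Earlier LPS by depletion difference, higher: 0 with RLE, no filter, block, sorter, day, RNA quality and neuron score, 11 with voom, 25 with DESeq2; lower 0 with RLE, no filter, sorter, day and RNA quality, 1 with block and neuron score, 32 on only the groups compared, 28 with voom, 27 with DESeq2. LPS by depletion difference, higher 1 (RLE), 5 (no filter), 2 (block), 69 (voom), 21 (DESeq2), 1 (neuron score); lower 6 (no filter), 131 (voom), 45 (DESeq2). The cause was not tested.

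Leaving out 1 library at a time gave, higher and lower: PL against PP 2046 to 2330 and 1713 to 1879; PBL against PBP 3024 to 4380 and 3145 to 3896; LL against PL 49 to 166 and 221 to 403; LBL against PBL 232 to 553 and 416 to 729; PBP against PP 25 to 65 and 24 to 44; PBL against PL 1060 to 2082 and 1123 to 2138; LBL against LL 36 to 120 and 49 to 164; LL against PP 2574 to 3125 and 1786 to 2132; LBL against PBP 1896 to 3334 and 1893 to 2671; earlier LPS by depletion 0 to 11 and 0 to 12 (highest without PL replicate 3); LPS by depletion 0 to 310 and 0 to 430 (highest without PBP replicate 5).

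Lists called at the preset correlation, with an estimated correlation, and when leaving out a library: PL against PP 8, 6 and 8 to 9; PBL against PBP 11, 4 and 11 to 11; LL against PL 16, 9 (8 with the sorter) and 15 to 18; LBL against PBL 10, 4 and 6 to 10; PBP against PP 8, 3 and 7 to 10; PBL against PL 10, 3 (6 with the neuron score) and 10 to 13; LBL against LL 9, 2 and 5 to 8; LL against PP 12, 0 and 10 to 13; LBL against PBP 10, 1 and 9 to 12; earlier LPS by depletion 8, 0 (1 with the neuron score) and 7 to 9; LPS by depletion 6, 0 (0 with day, 1 with the neuron score) and 5 to 11. Cell type scores under the threshold without 1 library: 2 to 3, 7 to 9, 5 to 7, 4 to 5, 2 to 3, 6 to 8 and 2 to 3 in the first 7 comparisons in that order.

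LPS lists: genes induced in depleted mice and lower in LL than in PL were 3 with the sorter and 145 with the neuron score, 153 to 252 without 1 library, and the list p was 0.0237 by adjusted p alone, 0.00204 at 4-fold, 2.1e-32 with the list from the same arm (which shares the PL libraries with the test, so that selection alone leans it downward), 0.0014 with the sorter, 5.12e-22 with the neuron score, 1.22e-47 with the XDP list (PBL against PBP replicate 5 alone) and 0.000324 to 0.972 without 1 library, the test pointing upward without PBP replicate 5 (0.0436) and PL replicate 3 (0.972) and downward otherwise. Lowered genes higher in LL were 14 at 4-fold, 36 from the same arm (PL shared), 0 with the sorter and 9 to 29 without 1 library; p was 0.162 with an estimated correlation, 0.742 by adjusted p alone, 0.5 with the sorter and 8.37e-06 to 0.0502. In LBL against PBL, induced genes lower were 202 at 4-fold and 243 to 347 (p 7.89e-40 to 5.33e-31), and lowered genes higher 194 by adjusted p alone, 18 at 4-fold, 199 from the same arm (PBL shared) and 51 to 96 (p 1.35e-12 to 4.94e-07). The correlation of the 2 earlier LPS effects was 0.368 at 5 CPM or more, 0.46 over genes called in either, 0.291 with the sorter, 0.299 with the neuron score and 0.106 to 0.238 without 1 library; genes lower in both were 8 with the sorter and 175 to 281. The cause was not tested.

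Direction turned with the sorter in the fit for Ch25h (4.58), Snap25 (-0.26), Camk2a (-0.51) and Clu (-0.63) in LL against PL, for S100a9 (-0.28), Rbfox3 (-0.68) and Tlr4 (0.11) in PBL against PL, and for Snap25 in PBL against PBP (-0.01; day -0.01; neuron score -0.17); with day for Rbfox3 (-0.38). Lists turned with the sorter: neurons (0.0114) and red blood cells (0.00821) in LL against PL, neurons (0.0107) and red blood cells (0.0107; day 0.0285) in the earlier LPS by depletion difference, and neurons (0.0384) in the LPS by depletion difference. The cause was not tested.

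Libraries with the same replicate number had a mean correlation of 0.015 across groups (-0.311 to 0.369; 8 of 70 pairs over 0.1) and other pairs -0.004 (280), and 6 of 29 libraries correlated best with their own number, so the numbers do not pair mice and the block was used here only. Depth limits genes near the floor: a gene with 0 counts in a group is below 0.07 to 0.101 CPM. Of genes changed 1.5-fold the simulations called 1.49% to 38.8%. They changed only genes above a minimum mean count, so they do not show the power near the floor.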

Other observations

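The sizes compared here follow predictions written before their results were seen, and no test of this part was chosen afterwards.

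Neutrophil genes were high in PBL alone, in all 5 of its libraries: Ngp, a granule protein gene of neutrophil precursors, was at 123 ± 57.5 CPM in PBL (SD, n = 5) and S100a8 at 78.6 ± 36.5 CPM, and Camp ranged from 14.9 to 78.4 CPM. The neutrophil score was 4.72 ± 0.69 in PBL, -0.45 ± 1.25 in PL, -0.82 ± 1.47 in LL and -1.21 ± 0.52 in LBL. PBP replicate 5, sorted with PBL but given no LPS, had -0.302. The scores of red blood cells were 2.87 in PBL, 2.7 in LL, 2.62 in LBL and 1.07 in PL.

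If earlier LPS damps the response in proportion, genes that LPS induces most should be lowered most. Genes were ranked by induction in the arm sharing no library with the effect tested. Of the 1181 genes induced in PL against PP, the 296 most induced had a median of -0.94 in LBL against PBL. The 296 least induced had -0.22, a difference of -0.72 (Spearman correlation -0.37 across genes). Of 2238 genes induced in PBL against PBP, the 560 most and 560 least induced had medians of -0.26 and -0.03 in LL against PL. The difference was -0.23 (Spearman -0.08). The first fits proportional dampening and the second leaves it open, with genes of other cells in its list.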
